A study of Mus musculus with 24 samples.

How the data were processed

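Interscapular brown fat of male C57BL/6 mice aged 10 to 12 weeks was collected at ZT10, a fixed hour of the light cycle, per the labels. RNA was extracted with TRIzol and RNeasy columns, ribosomal RNA was removed with Ribo-Zero, and libraries were made with a TruSeq kit, per the labels' protocols. Ribosomal depletion keeps transcripts without a poly(A) tail as well as unprocessed ones. Each library was placed in its group by its own label, which gave 4 libraries in each of 6 groups (Control and KO, at 22 °C, at 24 h and at 7 d of recovery).

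The submitters' processing notes name STAR, featureCounts and edgeR and the mouse build mm9, without versions or settings, so the counting of shared reads and of strand is not given in the sources used here. The authors deposited 5 tables, each comparing a pair of groups. Per the file headers, each table holds a log2 fold change, an average log2 CPM, a p-value with its adjusted p-value (false discovery rate), the gene length and a mean per group. The log2 fold change of the authors is the second-named group over the first, with their normalization factors. The p-value deposited by the authors comes from edgeR, and which of its tests was run is not given in the sources used here. The average log2 CPM of the authors is shared by all tables, as from a fit over all libraries. The deposited group means carry no unit in the file headers. They were read as RPKM because the CPM rebuilt from them with gene length lay at a nearly constant gap from the deposited value. The median log2 of the rebuilt mean CPM minus the deposited value was -0.51 (quartiles -0.55 and -0.50). The cause of this gap was not tested. These RPKM means of the authors leave out the normalization factors, so a ratio of means differs from the deposited fold change by a constant per table, with medians of -0.064 and 0.034 log2 for recovery in Control and KO, and -0.24, -0.14 and -0.066 for KO against Control at 22 °C, 24 h and 7 d.

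Each table lists the genes with a mean of at least 0.5 RPKM in the higher group, and the authors' adjustment ran over 13414 genes, more than any table lists. In all, 13162 genes appeared in any table and 11917 in all 5. No mitochondrial-encoded gene was listed. Of the symbols, 12632 (96.0%) were found in the reference annotation, which is of another build than mm9, so no coordinates are given. Fold changes added up around the 4 groups of the 22 °C and 24 h tables to within 0.045 log2 for 12069 genes. Library totals were recovered from the smallest steps of the deposited means of genes with few reads. They cannot be tied to replicate numbers, and no counts per library were rebuilt. Listed genes hold 65.5% to 75.6% of these totals.

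Because the tables hold no library values, the designed count test was not run and the authors' adjusted p from edgeR at 0.05 is the main result of each comparison. Before the data were examined, 45 gene lists, the comparisons, the threshold and the rule for named genes were fixed. The rule names Hdac3 and Ucp1, then up to 8 genes per direction with the largest deposited log2 fold change among those past the threshold with an average log2 CPM of at least 1. It adds up to 4 members with the smallest p from each list that passed its test or had 3 or more members past the threshold. Predicted loci and small RNAs were passed over. Some genes that this rule names are left out of the text. Means of Fasn and Acly over time, and the genes named for calls shared between tables, were chosen after their values were seen.

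Lists with at least 5 listed members were tested with cameraPR of limma 3.58.1 in R 4.3.3, on the signed normal score of the authors' p, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. An estimated correlation needs library values and was not run, so a correlation of 0.05 was tried instead, and its p is printed where it ends a call. Beside each count over all genes stands the count adjusted over the list alone, from the deposited p of the members. For 27 of 215 list tests, none past the threshold, the median, the mean and the test differed in sign. In 20 simulated comparisons on 13162 genes with members shifted by 1 SD, the list test recovered 87 of 100 shifted lists, 0 of them in the wrong direction, and called 1 of 647 others. The simulated scores were independent between genes. They therefore do not give the rate of false calls for lists whose members move together.

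Differences in KO effect between 22 °C and recovery were tested for lists alone, with a test added after the data were seen. The difference of the deposited log2 fold changes was divided by an error rebuilt from each deposited p (log2 fold change over its normal score, for p up to 0.9) and given to cameraPR. For 9406 genes the error of the 24 h difference could be rebuilt from either pairing of the tables, and the ratio of the results had a median of 1.000 (quartiles 0.988 and 1.01). Levels at 7 d against 22 °C were the median over a list of log2 ratios of mean RPKM plus 0.1, centred on the median of all genes (-0.047 and -0.11 at 24 h and 7 d in Control, 0.0100 and 0.047 in KO). Each median was ranked among 10000 random lists matched in 20 bins of average log2 CPM. The pseudocount makes ratios of low genes smaller than they are.

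Alternatives were an adjusted p under 0.01, a minimum absolute log2 fold change of 1, an average log2 CPM of at least 1, rank-based camera and Spearman's rho. Alternatives added after the data were seen were the authors' own up and down calls (adjusted p under 0.01 and over 1.5-fold), adjustment over the listed genes alone, ratios of mean RPKM, the inter-gene correlation of 0.05, a pseudocount of 1, list members with equal fold changes counted once, and medians over the members with a ratio at both times. Not run, because they need library values, were a second count test, other library scaling, a fit of all libraries, a block of replicate numbers, leaving out single libraries and other splits of the samples. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.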

Results

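RNA sequencing was done on interscapular brown adipose tissue, the heat-producing fat pad between the shoulder blades, from male C57BL/6 mice. Control mice carried floxed Hdac3 alleles, and knockout (KO) mice carried the same alleles with a Cre recombinase driven by the Ucp1 promoter, which acts in brown adipocytes. Hdac3 encodes a histone deacetylase that works within nuclear receptor corepressor complexes. Mice of each genotype stayed at 22 °C, or were held at 15 °C for 24 h and returned to 22 °C for 24 h or for 7 d, which gave 6 groups of 4 libraries and 24 libraries in all. The design asks what remains of a short cold exposure in brown fat, and how this depends on Hdac3.

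The authors deposited 5 tables of comparisons, with their fold changes, adjusted p-values and group means in RPKM (reads scaled to gene length and library total), and these authors' values underlie each gene named in what follows. The deposited tables hold no value per library, so no spread between replicates can be printed beside a mean, and the authors' adjusted p carries the replicate error. Library totals, recovered from the steps of the deposited means of rarely read genes, ran from 4.64e+06 to 1.25e+07 reads, with a mean of 8.39e+06 ± 1.90e+06 (SD, n = 24). The shallowest library belonged to the Control group at 7 d, whose totals averaged 7.46e+06 ± 3.51e+06 (SD, n = 4). Listed genes took 65.5% of the total in the KO group at 22 °C and 75.6% in the KO group at 7 d, the lowest and highest of the 6 groups. At the mean total, a gene 1 kb long at 1 RPKM rests on 8.39 reads per library, so levels near 0 are imprecise. The labels used here do not say whether each library came from its own mouse, so the p-values measure the spread between libraries.

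The targeted gene was lower in the KO at every time. In the authors' deposited tables Hdac3 averaged 26.1 RPKM in Control and 8.57 in KO at 22 °C (2.59-fold lower, adjusted p = 9.9e-21). It was 3.82-fold (adjusted p = 4.6e-37) lower in the KO after 24 h of recovery and 3.26-fold (adjusted p = 6.4e-29) lower after 7 d in the deposited tables. The remaining deposited level in the KO, 6.43 RPKM at 24 h and 7.43 at 7 d, was measured in whole tissue, which also holds cells without the Cre. Within Control, the deposited Hdac3 means at 22 °C and at 24 h of recovery did not differ past the threshold (adjusted p = 0.605).

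**Figure D1:**
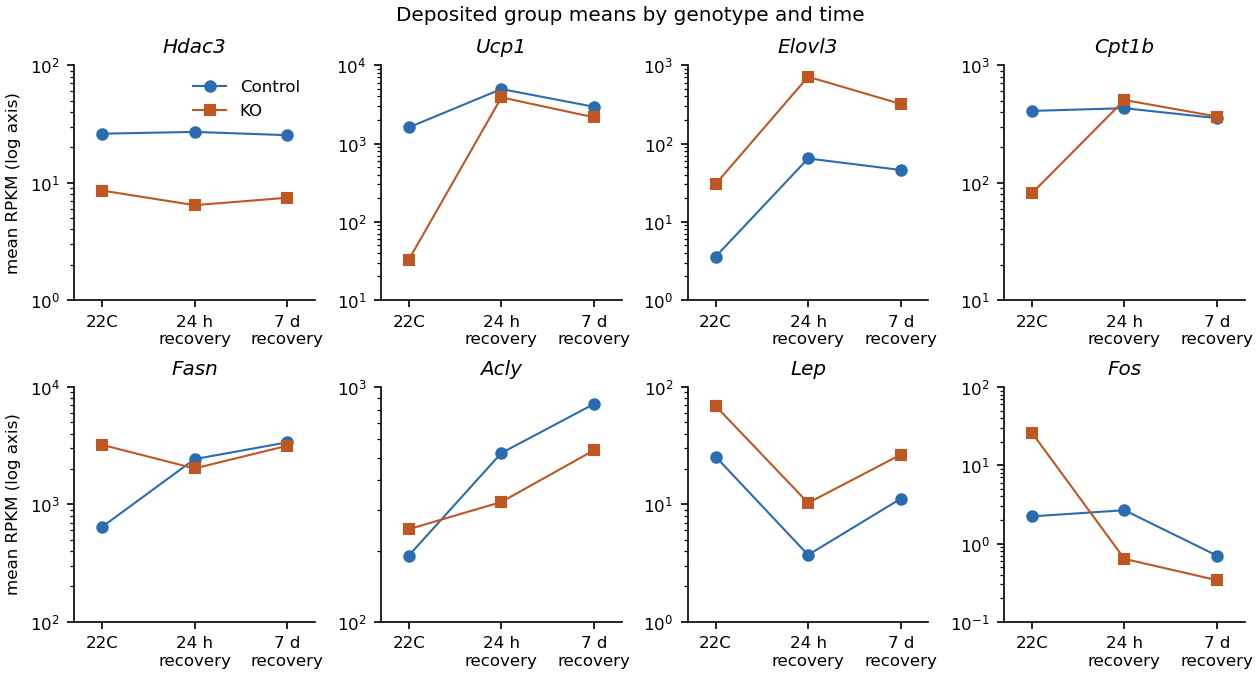
The authors' mean RPKM (log axes) of 8 genes is plotted by time for Control (circles) and KO (squares). Ucp1 in the KO stood at 32.8 at 22 °C and 3884 after 24 h of recovery, against 1607 and 4966 in Control, and the tables give no spread, so no error bars are drawn.

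In Control mice, brown fat 24 h after the cold exposure carried more transcripts of lipogenic and glycolytic genes than brown fat kept at 22 °C. Ucp1, the uncoupling protein that turns the proton gradient into heat, was 3.16-fold (adjusted p = 1.4e-04) higher in the authors' deposited table, with means of 1607 and 4966 RPKM. Elovl3, an elongase of very long chain fatty acids that cold induces, was 17.9-fold (adjusted p = 3.0e-12) higher, and Bmp8b, a secreted factor of thermogenic fat, was listed at 0 at 22 °C and at 2.10 RPKM after recovery in the deposited table. Lep, which encodes the hormone leptin, was 6.55-fold (adjusted p = 1.2e-05) lower, and the immediate early nuclear receptor gene Nr4a1 was 7.69-fold (adjusted p = 1.2e-04) lower, as deposited. Across the 12830 listed genes, 1682 were higher and 1113 lower after recovery at the authors' adjusted p under 0.05, which is 21.8% of them.

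Genes of de novo lipogenesis, which build fatty acids from citrate, rose together in Control, with 17 of 21 members higher and 0 lower (17 and 0 adjusted over the list alone). De novo lipogenesis genes had a median log2 fold change of 1.01 (adjusted p of the list = 1.2e-13). The deposited folds were 3.98 for malic enzyme Me1, 3.02 for the citrate carrier Slc25a1 and 2.32 for the NADPH source G6pdx. Glycolysis and glucose uptake had 16 of 25 members higher and 0 lower (16 and 1 adjusted over the list alone). Glycolysis and glucose uptake genes had a median log2 fold change of 0.74 (adjusted p of the list = 2.7e-14). Among its members, Gapdh was 3.48-fold (adjusted p = 7.0e-19) higher and Ldha 2.54-fold (adjusted p = 2.6e-13) higher in the authors' deposited table. Skeletal muscle markers had a median log2 fold change of 0.85 in the same comparison, with no member past the threshold (adjusted p of the list = 0.585). Whether muscle taken with the fat pad added to these glycolytic values was not tested. Pyruvate import and TCA cycle genes had 16 of 33 members higher and 2 lower (17 and 2 adjusted over the list alone), including the pyruvate carrier subunit Mpc2 at 2.69-fold and the dehydrogenase subunit Pdhb at 2.55-fold as deposited. Pyruvate and TCA cycle genes had a median log2 fold change of 0.33 (adjusted p of the list = 1.1e-07). Nuclear genes of oxidative phosphorylation had 34 of 79 members higher and 0 lower (39 and 0 adjusted over the list alone), with smaller deposited folds such as 1.93 for Ndufb7. Oxidative phosphorylation genes had a median log2 fold change of 0.34 (adjusted p of the list = 1.4e-10). The mitochondrial ribosome had 25 of 58 members higher and 0 lower (33 and 0 adjusted over the list alone). Mitochondrial ribosome genes had a median log2 fold change of 0.34 (adjusted p of the list = 9.4e-10). Fatty acid oxidation had 14 of 31 members higher and 1 lower (15 and 1 adjusted over the list alone). Fatty acid oxidation genes had a median log2 fold change of 0.31 (adjusted p of the list = 1.2e-04). Cholesterol synthesis had 8 of 21 members higher and 1 lower (9 and 1 adjusted over the list alone). Cholesterol synthesis genes had a median log2 fold change of 0.38 (adjusted p of the list = 3.2e-04). Triglyceride synthesis genes had 9 of 16 members higher and 1 lower (9 and 2 adjusted over the list alone), with Agpat2 2.5-fold and the glycerol phosphate dehydrogenase Gpd1 2.33-fold higher as deposited. Triglyceride synthesis genes had a median log2 fold change of 0.50 (adjusted p of the list = 0.0046). The thermogenic list was divided, with 11 of 27 members higher and 3 lower (11 and 3 adjusted over the list alone). Thermogenic programme genes had a median log2 fold change of 0.14 (adjusted p of the list = 0.013 but 0.220 by ranks and 0.103 with an inter-gene correlation of 0.05). Its lower members in the deposited table included Ppara, a receptor that drives fat oxidation, at 2.33-fold (adjusted p = 1.3e-13) lower, while the mitochondrial protein gene Letmd1 was 2.52-fold (adjusted p = 2.4e-14) higher.

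Macrophage, proliferation and extracellular matrix genes also rose in Control, while vascular endothelium, fibroblast, smooth muscle and neutrophil genes did not pass the test of lists (lowest adjusted p of these lists = 0.772). Macrophage markers had 19 of 26 members higher and 0 lower (20 and 0 adjusted over the list alone), and the deposited table gave Lgals3 as 10.8-fold (adjusted p = 2.3e-07) higher, Cd68 as 4.76-fold (adjusted p = 3.4e-05) higher and Trem2 as 15.0-fold (adjusted p = 4.7e-04) higher. Macrophage genes had a median log2 fold change of 1.02 (adjusted p of the list = 5.7e-08). The chemokine genes Ccl2 and Ccl7 were 11.3-fold (adjusted p = 0.0026) and 8.95-fold (adjusted p = 0.0016) higher in the deposited table, in a list of inflammatory cytokines with 6 of 23 members higher and 0 lower (6 and 0 adjusted over the list alone). Inflammatory cytokine genes had a median log2 fold change of 0.60 (adjusted p of the list = 0.032 but 0.151 with an inter-gene correlation of 0.05). Proliferation genes had 22 of 34 members higher and 0 lower (27 and 0 adjusted over the list alone), among them Mki67 at 5.56-fold and the topoisomerase Top2a at 7.04-fold as deposited, although Mki67 reached 2.86 RPKM. Cell cycle genes had a median log2 fold change of 1.77 (adjusted p of the list = 6.0e-10). Only 16 members were listed in KO against Control at 22 °C, so some of the 34 were listed through their 24 h level alone. Members listed that way are higher by selection, which raises the count and the median. In centred ratios of mean RPKM, the median was 1.52 over the 34 and 0.72 over the 19 members that also had a ratio at 7 d. Extracellular matrix genes had 23 of 38 members higher and 1 lower (26 and 1 adjusted over the list alone), with deposited folds of 4.29 for the collagen cross-linking gene Loxl1 and 2.01 for the basement membrane collagen Col4a1. Extracellular matrix genes had a median log2 fold change of 0.76 (adjusted p of the list = 2.2e-09). Mature adipocyte identity genes had 2 of 19 members higher and 6 lower (2 and 6 adjusted over the list alone). Mature adipocyte identity genes had a median log2 fold change of -0.17 (adjusted p of the list = 0.043 but 0.095 by ranks and 0.153 with an inter-gene correlation of 0.05). Erythroid genes had 0 of 9 members higher and 0 lower (0 and 0 adjusted over the list alone). Erythroid genes had a median log2 fold change of -0.58 (adjusted p of the list = 0.039 but 0.103 with an inter-gene correlation of 0.05 and 0.097 with globin genes of equal fold changes counted once). Oxidative stress defence genes had 12 of 29 members higher and 2 lower (12 and 2 adjusted over the list alone). Oxidative stress defence genes had a median log2 fold change of 0.26 (adjusted p of the list = 0.027 but 0.151 with an inter-gene correlation of 0.05). Clock genes moved both ways, with 5 of 22 members higher and 7 lower (5 and 9 adjusted over the list alone), and the deposited Arntl was 7.66-fold (adjusted p = 8.9e-17) higher while Dbp was 1.99-fold (adjusted p = 1.9e-09) lower. Circadian clock genes had a median log2 fold change of -0.26 (adjusted p of the list = 0.106).

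In KO mice, the same recovery was accompanied by a large rise of mitochondrial and thermogenic transcripts. The deposited Ucp1 mean went from 32.8 RPKM at 22 °C to 3884 after 24 h of recovery, 114-fold (adjusted p = 1.3e-46) higher. Cox7a1, a cytochrome oxidase subunit of heart, muscle and brown fat, was 15.3-fold (adjusted p = 2.0e-82) higher, Cpt1b, which takes fatty acids toward mitochondria, 6.10-fold (adjusted p = 5.1e-62) higher and Fabp3, a fatty acid carrier, 37.3-fold (adjusted p = 8.2e-37) higher in the authors' deposited table. Immediate early genes went the other way, with Fos 41.8-fold (adjusted p = 5.0e-06) lower and Egr1 26.8-fold (adjusted p = 1.7e-05) lower as deposited. Of 12577 listed genes, 2780 were higher and 2496 lower, 42.0% of them, at the authors' adjusted p under 0.05.

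The thermogenic list had 24 of 27 members higher and 0 lower (24 and 0 adjusted over the list alone), and its deposited folds included 29.8 for the thioesterase Acot11 and 10.7 for Letmd1. Thermogenic programme genes had a median log2 fold change of 2.03 (adjusted p of the list = 2.5e-28). Oxidative phosphorylation had 74 of 79 members higher and 0 lower (74 and 0 adjusted over the list alone), with Cycs, which encodes cytochrome c, 5.50-fold higher and complex I subunit Ndufb6 4.10-fold higher as deposited. Oxidative phosphorylation genes had a median log2 fold change of 1.24 (adjusted p of the list = 2.1e-49). Fatty acid oxidation had 25 of 31 members higher and 1 lower (27 and 1 adjusted over the list alone), including Acaa2 at 7.65-fold and the carnitine carrier Slc25a20 at 4.97-fold in the deposited table. Fatty acid oxidation genes had a median log2 fold change of 1.34 (adjusted p of the list = 5.5e-21). The pyruvate and TCA cycle list had 28 of 33 members higher and 2 lower (28 and 2 adjusted over the list alone), with Idh3a 6.03-fold (adjusted p = 6.3e-79) higher in the deposited table. Pyruvate and TCA cycle genes had a median log2 fold change of 1.37 (adjusted p of the list = 3.7e-23). The mitochondrial ribosome had 55 of 58 members higher and 0 lower (55 and 0 adjusted over the list alone). Mitochondrial ribosome genes had a median log2 fold change of 0.98 (adjusted p of the list = 2.8e-27). Glycolysis and glucose uptake had 16 of 23 members higher and 2 lower (16 and 2 adjusted over the list alone), with Ldhb 11.7-fold (adjusted p = 1.2e-103) higher as deposited. Glycolysis and glucose uptake genes had a median log2 fold change of 1.20 (adjusted p of the list = 4.2e-15). Gyk, which phosphorylates glycerol, was 38.3-fold (adjusted p = 6.1e-32) higher and Gpd1 7.10-fold (adjusted p = 2.0e-40) higher in the deposited table, within a triglyceride synthesis list that had 11 of 17 members higher and 4 lower (11 and 5 adjusted over the list alone). Triglyceride synthesis genes had a median log2 fold change of 0.66 (adjusted p of the list = 0.015 but 0.101 by ranks and 0.081 with an inter-gene correlation of 0.05). De novo lipogenesis had 5 of 21 members higher and 7 lower (5 and 7 adjusted over the list alone), and its regulator Srebf1 was 2.39-fold (adjusted p = 1.8e-13) lower as deposited. De novo lipogenesis genes had a median log2 fold change of 0.0010 (adjusted p of the list = 0.756). Creatine and calcium cycling genes had 6 of 13 members higher and 2 lower (6 and 2 adjusted over the list alone), including Ckb at 10.1-fold and Alpl at 6.92-fold higher as deposited, and branched-chain amino acid catabolism had 10 of 22 members higher and 2 lower (10 and 2 adjusted over the list alone). Creatine and calcium cycling genes had a median log2 fold change of 0.34 (adjusted p of the list = 0.023 but 0.165 by ranks and 0.086 with an inter-gene correlation of 0.05). Branched-chain amino acid catabolism genes had a median log2 fold change of 0.18 (adjusted p of the list = 0.021 but 0.112 with an inter-gene correlation of 0.05).

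Immediate early genes, which cells switch on within minutes of a stimulus, had 0 of 23 members higher and 20 lower (0 and 20 adjusted over the list alone) in the KO after recovery. These immediate early genes had a median log2 fold change of -2.29 (adjusted p of the list = 3.1e-07). The deposited means of Fos were 26.1 RPKM at 22 °C and 0.637 after recovery, and those of Nr4a1 were 51.4 and 2.5. Clock genes had 3 of 22 members higher and 12 lower (4 and 14 adjusted over the list alone), with Per1 2.57-fold (adjusted p = 4.1e-09) lower and Cry2 2.34-fold (adjusted p = 2.2e-13) lower in the deposited table. Circadian clock genes had a median log2 fold change of -0.50 (adjusted p of the list = 0.0034). Heat shock genes and chaperones had 9 of 19 members higher and 1 lower (9 and 1 adjusted over the list alone), with the mitochondrial chaperone Hspd1 3.35-fold (adjusted p = 1.4e-47) higher as deposited. Heat shock and chaperone genes had a median log2 fold change of 0.27 (adjusted p of the list = 0.0051). Cell cycle genes had 17 of 30 members higher and 0 lower (21 and 0 adjusted over the list alone), with low deposited levels such as 1.58 RPKM for Rrm2. Cell cycle genes had a median log2 fold change of 1.31 (adjusted p of the list = 0.0062 but 0.081 with an inter-gene correlation of 0.05). As in Control, some of these members were listed through their 24 h level alone and are higher by selection. Among markers of other cells, macrophage genes had 0 of 25 members higher and 1 lower (0 and 1 adjusted over the list alone). Macrophage genes had a median log2 fold change of 0.28 (adjusted p of the list = 0.877). Fibroblast and progenitor genes had 1 of 16 members higher and 8 lower (1 and 8 adjusted over the list alone). Fibroblast and adipocyte progenitor genes had a median log2 fold change of -0.45 (adjusted p of the list = 0.0696 but 0.046 by ranks). Class II antigen presentation genes had 0 of 8 members higher and 4 lower (0 and 4 adjusted over the list alone). Antigen presentation class II genes had a median log2 fold change of -0.71 (adjusted p of the list = 0.119 but 0.032 by ranks). The adipocyte identity list had 3 of 19 members higher and 7 lower (4 and 9 adjusted over the list alone), with Cfd, which encodes adipsin, 4.19-fold (adjusted p = 3.2e-15) lower and Adipoq, which encodes adiponectin, 1.97-fold (adjusted p = 1.3e-07) lower as deposited. Mature adipocyte identity genes had a median log2 fold change of -0.30 (adjusted p of the list = 0.210).

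**Figure D2:**
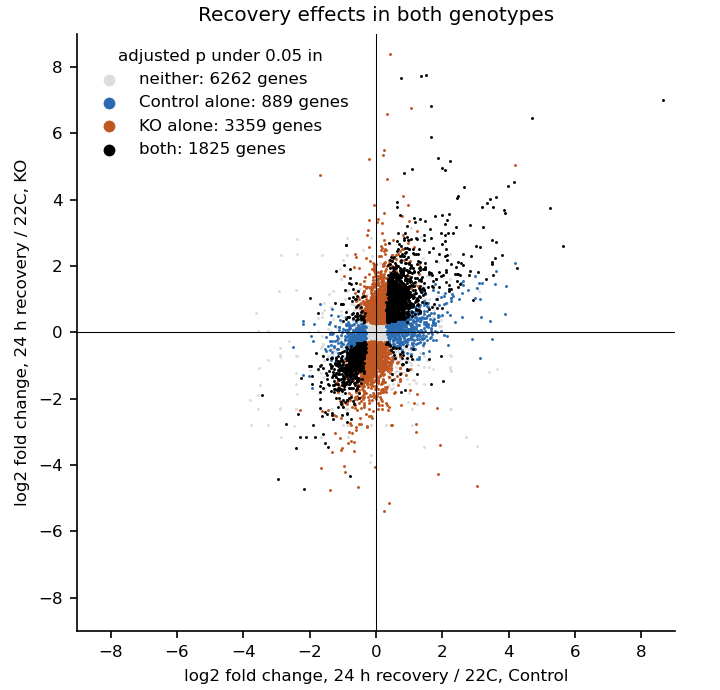
Each point is 1 of 12335 genes, with the authors' log2 fold change of recovery 24 h against 22 °C in Control on the horizontal axis and in KO on the vertical axis. Genes past an adjusted p of 0.05 in both genotypes (1825), in Control alone (889), in KO alone (3359) or in neither (6262) are coloured apart.

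Recovery effects in Control and KO came from separate libraries and were compared over the 12335 genes listed in both. Of 1638 genes higher in Control and 2753 higher in KO, 1057 were shared, where independent lists would share 366. Lower genes shared 665 against 212 for independent lists. Opposite calls were 39 genes higher in Control and lower in KO and 64 the other way, against 323 and 240.2. Across genes, which are not independent replicates, the deposited log2 fold changes had a Pearson r of 0.494 and a Spearman rho of 0.523. Bmp8b and Loxl1 were among the genes higher in both deposited tables, and Lep and Nr4a1 among those lower in both.

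At 22 °C, with no cold exposure, KO brown fat had far fewer transcripts of thermogenic and mitochondrial genes than Control, and more of lipogenic ones. The deposited Ucp1 mean was 1607 RPKM in Control and 32.8 in KO, 41.9-fold (adjusted p = 4.2e-33) lower. Cox7a1 was 13.9-fold (adjusted p = 1.5e-77) lower, Acaa2, the last enzyme of mitochondrial fat oxidation, 10.00-fold (adjusted p = 9.3e-81) lower and Fabp3 18.5-fold (adjusted p = 2.7e-26) lower in the authors' deposited table. The sterol sensor gene Insig1 was 8.08-fold (adjusted p = 3.6e-43) higher as deposited. Of 12710 listed genes, 2074 were higher and 2282 lower in KO, 34.3% of them, at the authors' adjusted p under 0.05. The log2 ratio of mean RPKM lay at a median of -0.24 from the authors' log2 fold change here, the largest such gap of the 5 deposited tables, and no gene past the threshold changed direction between these scales.

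Oxidative phosphorylation had 2 of 79 members higher and 76 lower (2 and 76 adjusted over the list alone), with the deposited complex I subunit Ndufv1 3.16-fold lower and the succinate dehydrogenase subunit Sdhb 2.95-fold lower. Oxidative phosphorylation genes had a median log2 fold change of -1.07 (adjusted p of the list = 9.9e-44). The thermogenic list had 2 of 26 members higher and 21 lower (2 and 21 adjusted over the list alone), with Letmd1 5.11-fold and Cpt1b 4.28-fold lower as deposited. Thermogenic programme genes had a median log2 fold change of -1.45 (adjusted p of the list = 8.8e-24). Fatty acid oxidation had 4 of 30 members higher and 21 lower (4 and 22 adjusted over the list alone). Fatty acid oxidation genes had a median log2 fold change of -0.88 (adjusted p of the list = 1.0e-08). The pyruvate and TCA cycle list had 3 of 33 members higher and 22 lower (4 and 24 adjusted over the list alone). Pyruvate and TCA cycle genes had a median log2 fold change of -0.86 (adjusted p of the list = 8.4e-13). The mitochondrial ribosome had 0 of 58 members higher and 38 lower (0 and 40 adjusted over the list alone). Mitochondrial ribosome genes had a median log2 fold change of -0.58 (adjusted p of the list = 4.5e-09). Glycolysis had 3 of 24 members higher and 14 lower (3 and 14 adjusted over the list alone). Glycolysis and glucose uptake genes had a median log2 fold change of -0.44 (adjusted p of the list = 6.4e-06). Creatine and calcium cycling genes had 0 of 12 members higher and 4 lower (0 and 4 adjusted over the list alone). Creatine and calcium cycling genes had a median log2 fold change of -0.22 (adjusted p of the list = 0.018 but 0.109 by ranks and 0.064 with an inter-gene correlation of 0.05). Lower deposited levels were also listed for the orphan receptor genes Esrrg (5.06-fold, adjusted p = 4.5e-25) and Esrra (2.11-fold, adjusted p = 4.8e-14), which act on mitochondrial genes, and for the mitochondrial deacetylase Sirt3 (2.81-fold, adjusted p = 2.7e-24). Lgr6 and Kng2 had deposited means of 11.0 and 38.0 RPKM in Control and 0.00753 and 0.0973 in KO.

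De novo lipogenesis was higher in KO at 22 °C, with 16 of 21 members higher and 0 lower (18 and 1 adjusted over the list alone), and deposited folds were 7.38 for Me1, 7.52 for the desaturase Scd2, 6.45 for Elovl5 and 2.84 for Srebf1. De novo lipogenesis genes had a median log2 fold change of 1.23 (adjusted p of the list = 6.2e-12). Cholesterol synthesis had 9 of 21 members higher and 3 lower (11 and 4 adjusted over the list alone). Cholesterol synthesis genes had a median log2 fold change of 0.51 (adjusted p of the list = 8.3e-04). Lipid uptake had 9 of 18 members higher and 3 lower (10 and 3 adjusted over the list alone), with the deposited lipoprotein lipase gene Lpl 4.33-fold (adjusted p = 3.8e-44) higher. Lipid uptake genes had a median log2 fold change of 0.50 (adjusted p of the list = 8.2e-04 but 0.057 by ranks). Lipolysis and lipid droplet genes had 8 of 17 members higher and 4 lower (8 and 5 adjusted over the list alone), and here the droplet protein Cidec was 4.31-fold (adjusted p = 5.0e-42) higher and Cidea, a droplet protein typical of brown fat, 2.68-fold (adjusted p = 1.1e-16) lower as deposited. Lipolysis and lipid droplet genes had a median log2 fold change of 0.35 (adjusted p of the list = 0.026 but 0.244 by ranks and 0.098 with an inter-gene correlation of 0.05). Mature adipocyte identity had 10 of 19 members higher and 2 lower (12 and 2 adjusted over the list alone), with Fabp4 2.36-fold (adjusted p = 2.5e-21) higher in the deposited table. Mature adipocyte identity genes had a median log2 fold change of 0.55 (adjusted p of the list = 4.5e-06). White adipocyte markers had 5 of 14 members higher and 2 lower (5 and 2 adjusted over the list alone), with the deposited Retn 6.19-fold (adjusted p = 1.4e-08) and Lep 3.21-fold (adjusted p = 0.0044) higher. White adipocyte markers had a median log2 fold change of 0.42 (adjusted p of the list = 0.235). Insulin signalling genes had 9 of 25 members higher and 3 lower (10 and 3 adjusted over the list alone). Insulin signalling genes had a median log2 fold change of 0.25 (adjusted p of the list = 0.014 but 0.092 with an inter-gene correlation of 0.05). The corepressor complex had 5 of 8 members higher and 1 lower (6 and 1 adjusted over the list alone), in which Hdac3 itself was the lower member and the deposited Tbl1x was 3.51-fold (adjusted p = 2.2e-42) higher. Nuclear receptor corepressor complex genes had a median log2 fold change of 0.55 (adjusted p of the list = 0.0019 but 0.0503 by ranks).

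Immediate early genes had 16 of 23 members higher and 0 lower (17 and 0 adjusted over the list alone) in KO at 22 °C, with deposited means of Fos at 2.22 RPKM in Control and 26.1 in KO (14.1-fold, adjusted p = 8.0e-04), and Btg2 6.73-fold (adjusted p = 9.2e-07) higher. These immediate early genes had a median log2 fold change of 1.55 (adjusted p of the list = 2.0e-04). Clock genes had 12 of 22 members higher and 0 lower (13 and 0 adjusted over the list alone), including Rora at 4.25-fold (adjusted p = 7.1e-40) higher as deposited. Circadian clock genes had a median log2 fold change of 0.50 (adjusted p of the list = 4.0e-05). Lymphocyte genes had 9 of 11 members higher and 0 lower (9 and 0 adjusted over the list alone), at low deposited levels such as 1.68 RPKM of Cd3g in KO and 0.291 in Control. Lymphocyte genes had a median log2 fold change of 1.998 (adjusted p of the list = 0.0068). Of the 24 genes in this list, only 4 were listed for recovery in Control, so most of those listed here entered through their KO level. Genes listed that way are higher in KO by selection, which raises the count and the median. Without low genes the list had too few members for a test. Interferon response genes had 9 of 28 members higher and 0 lower (9 and 0 adjusted over the list alone), with Usp18 9.47-fold (adjusted p = 1.5e-10) higher in the deposited table, and class II antigen presentation genes had 5 of 8 members higher and 0 lower (5 and 0 adjusted over the list alone). Interferon response genes had a median log2 fold change of 0.44 (adjusted p of the list = 0.0069 but 0.069 with an inter-gene correlation of 0.05). Antigen presentation class II genes had a median log2 fold change of 0.68 (adjusted p of the list = 0.105 but 0.011 by ranks). Macrophage genes had 3 of 26 members higher and 0 lower (3 and 0 adjusted over the list alone). Macrophage genes had a median log2 fold change of 0.47 (adjusted p of the list = 0.105 but 0.0075 by ranks). Vascular endothelium genes had 1 of 21 members higher and 0 lower (1 and 0 adjusted over the list alone). Vascular endothelium genes had a median log2 fold change of -0.024 (adjusted p of the list = 0.856). Heat shock genes had 2 of 18 members higher and 2 lower (2 and 2 adjusted over the list alone). Heat shock and chaperone genes had a median log2 fold change of -0.025 (adjusted p of the list = 0.856). S100b, listed as a Schwann cell marker, was 26.8-fold (adjusted p = 2.6e-70) lower as deposited, in a list with 2 of 10 members higher and 2 lower (2 and 2 adjusted over the list alone). Schwann cell and nerve genes had a median log2 fold change of 0.25 (adjusted p of the list = 0.566).

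After 24 h of recovery, Ucp1 did not differ between genotypes past the threshold, with deposited means of 4966 RPKM in Control and 3884 in KO (adjusted p = 0.779). Lipid uptake and storage genes were higher in KO, with the lipid droplet coat protein gene Plin2 4.76-fold (adjusted p = 1.6e-25) higher and Lpl 2.70-fold (adjusted p = 1.1e-20) higher in the authors' deposited table. Ehhadh, of peroxisomal fat oxidation, was 6.22-fold (adjusted p = 1.5e-26) higher as deposited. Elovl3 was 12.2-fold (adjusted p = 2.4e-10) higher and Adrb3, the beta-3 adrenergic receptor of fat, 2.95-fold (adjusted p = 7.7e-09) higher, while Gmpr, in the thermogenic list, was 6.13-fold (adjusted p = 1.6e-07) lower in the deposited table. Of 12657 listed genes, 1335 were higher and 1007 lower in KO, 18.5% of them, at the authors' adjusted p under 0.05.

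Lipid uptake had 12 of 18 members higher and 2 lower (12 and 2 adjusted over the list alone), with Fabp5 5.32-fold and the lipoprotein receptor Vldlr 2.95-fold higher as deposited. Lipid uptake genes had a median log2 fold change of 0.97 (adjusted p of the list = 2.3e-11). Mature adipocyte identity had 13 of 19 members higher and 1 lower (14 and 1 adjusted over the list alone), including Cebpa, an adipocyte transcription factor gene, at 1.95-fold (adjusted p = 2.0e-07) higher as deposited. Mature adipocyte identity genes had a median log2 fold change of 0.55 (adjusted p of the list = 2.7e-11). Triglyceride synthesis had 9 of 17 members higher and 1 lower (13 and 2 adjusted over the list alone), with Dgat2 1.99-fold higher and Acsl5 3.21-fold lower in the deposited table, and lipolysis and lipid droplet genes had 6 of 16 members higher and 1 lower (8 and 1 adjusted over the list alone). Triglyceride synthesis genes had a median log2 fold change of 0.53 (adjusted p of the list = 2.9e-05). Lipolysis and lipid droplet genes had a median log2 fold change of 0.29 (adjusted p of the list = 2.4e-04). The thermogenic list had 7 of 27 members higher and 4 lower (9 and 6 adjusted over the list alone). Thermogenic programme genes had a median log2 fold change of 0.017 (adjusted p of the list = 0.254). De novo lipogenesis had 8 of 21 members higher and 4 lower (8 and 4 adjusted over the list alone). De novo lipogenesis genes had a median log2 fold change of 0.28 (adjusted p of the list = 0.057). Fatty acid oxidation had 8 of 31 members higher and 2 lower (10 and 3 adjusted over the list alone). Fatty acid oxidation genes had a median log2 fold change of 0.19 (adjusted p of the list = 0.011 but 0.094 with an inter-gene correlation of 0.05). Oxidative phosphorylation had 2 of 79 members higher and 14 lower (2 and 15 adjusted over the list alone). Oxidative phosphorylation genes had a median log2 fold change of -0.13 (adjusted p of the list = 0.018 but 0.173 with an inter-gene correlation of 0.05). The mitochondrial ribosome had 13 of 58 members higher and 3 lower (14 and 5 adjusted over the list alone). Mitochondrial ribosome genes had a median log2 fold change of 0.12 (adjusted p of the list = 0.019 but 0.173 with an inter-gene correlation of 0.05). Unfolded protein response genes had 15 of 26 members higher and 2 lower (17 and 2 adjusted over the list alone), with the endoplasmic reticulum stress genes Dnajb9 3.94-fold (adjusted p = 5.6e-21) and Creld2 2.20-fold (adjusted p = 3.3e-04) higher as deposited, and heat shock genes had 8 of 19 members higher and 0 lower (10 and 0 adjusted over the list alone). Unfolded protein response genes had a median log2 fold change of 0.49 (adjusted p of the list = 2.0e-06). Heat shock and chaperone genes had a median log2 fold change of 0.37 (adjusted p of the list = 2.7e-04). Clock genes had 9 of 22 members higher and 2 lower (10 and 4 adjusted over the list alone). Circadian clock genes had a median log2 fold change of 0.22 (adjusted p of the list = 0.014 but 0.094 with an inter-gene correlation of 0.05). Immediate early genes had 0 of 20 members higher and 1 lower (0 and 0 adjusted over the list alone). These immediate early genes had a median log2 fold change of -0.31 (adjusted p of the list = 0.256).

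Extracellular matrix genes had 3 of 38 members higher and 16 lower (3 and 23 adjusted over the list alone) in KO at 24 h, with the collagen genes Col5a2 2.11-fold (adjusted p = 9.3e-04) lower and Col6a2 1.86-fold (adjusted p = 7.3e-04) lower as deposited, and Lamb1 1.82-fold (adjusted p = 1.9e-06) higher. Extracellular matrix genes had a median log2 fold change of -0.62 (adjusted p of the list = 1.1e-04). Fibroblast and progenitor genes had 0 of 17 members higher and 3 lower (0 and 3 adjusted over the list alone). Fibroblast and adipocyte progenitor genes had a median log2 fold change of -0.35 (adjusted p of the list = 0.026 but 0.119 with an inter-gene correlation of 0.05). Smooth muscle and pericyte genes had 0 of 15 members higher and 4 lower (0 and 4 adjusted over the list alone). Smooth muscle and pericyte genes had a median log2 fold change of -0.31 (adjusted p of the list = 0.019 but 0.094 with an inter-gene correlation of 0.05). Macrophage genes had 0 of 26 members higher and 2 lower (0 and 0 adjusted over the list alone). Macrophage genes had a median log2 fold change of -0.42 (adjusted p of the list = 0.019 but 0.119 with an inter-gene correlation of 0.05). Inflammatory cytokine genes had 2 of 23 members higher and 6 lower (2 and 6 adjusted over the list alone), with Ccl2 10.9-fold (adjusted p = 0.0032) lower as deposited, and neutrophil and mast cell genes had 0 of 9 members higher and 2 lower (0 and 3 adjusted over the list alone). Inflammatory cytokine genes had a median log2 fold change of -0.46 (adjusted p of the list = 0.0398 but 0.162 with an inter-gene correlation of 0.05 and 0.060 with an average log2 CPM of at least 1). Neutrophil and mast cell genes had a median log2 fold change of -0.66 (adjusted p of the list = 0.026 but 0.094 with an inter-gene correlation of 0.05). Interferon response genes had 8 of 29 members higher and 0 lower (10 and 0 adjusted over the list alone), with Igtp 2.96-fold (adjusted p = 0.0016) and Gbp2 2.44-fold (adjusted p = 0.0011) higher in the deposited table. Interferon response genes had a median log2 fold change of 0.44 (adjusted p of the list = 0.0041 but 0.067 with an inter-gene correlation of 0.05). Cell cycle genes had 1 of 34 members higher and 0 lower (0 and 0 adjusted over the list alone). Cell cycle genes had a median log2 fold change of -0.33 (adjusted p of the list = 0.395).

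After 7 d of recovery, genes of lipid uptake and storage were still higher in KO than in Control. Lpl was 3.03-fold (adjusted p = 3.5e-25) higher, Plin2 4.4-fold (adjusted p = 3.1e-23) higher and Apoe, which encodes a lipoprotein component, 5.51-fold (adjusted p = 3.1e-23) higher in the authors' deposited table. Hmox1, the inducible heme oxygenase gene, was 11.8-fold (adjusted p = 3.0e-04) higher as deposited. The deposited Ucp1 means were 2948 RPKM in Control and 2163 in KO (adjusted p = 0.578), while Elovl3 was 7.32-fold (adjusted p = 5.3e-07) higher. Of 12467 listed genes, 1144 were higher and 766 lower, 15.3% of them, at the authors' adjusted p under 0.05.

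Lipid uptake had 11 of 18 members higher and 1 lower (12 and 1 adjusted over the list alone). Lipid uptake genes had a median log2 fold change of 0.78 (adjusted p of the list = 4.5e-12). Mature adipocyte identity had 8 of 19 members higher and 0 lower (10 and 1 adjusted over the list alone), with Cidec 3.05-fold (adjusted p = 2.2e-24) and Fabp4 2.19-fold (adjusted p = 6.3e-17) higher as deposited. Mature adipocyte identity genes had a median log2 fold change of 0.47 (adjusted p of the list = 1.0e-08). Lipolysis and lipid droplet genes had 8 of 17 members higher and 1 lower (9 and 1 adjusted over the list alone). Lipolysis and lipid droplet genes had a median log2 fold change of 0.36 (adjusted p of the list = 2.3e-05). Triglyceride synthesis had 8 of 17 members higher and 1 lower (9 and 1 adjusted over the list alone), in which Acsl5 was 4.63-fold (adjusted p = 2.7e-09) lower in the deposited table. Triglyceride synthesis genes had a median log2 fold change of 0.60 (adjusted p of the list = 5.0e-04). Integrated stress response genes had 12 of 27 members higher and 0 lower (14 and 0 adjusted over the list alone), with the transcription factor gene Atf4 1.96-fold (adjusted p = 4.2e-04) and the amino acid transporter gene Slc3a2 3.16-fold (adjusted p = 1.8e-11) higher as deposited. Integrated stress response genes had a median log2 fold change of 0.50 (adjusted p of the list = 1.6e-05). Heat shock genes and chaperones had 10 of 19 members higher and 0 lower (13 and 0 adjusted over the list alone), including Hsp90aa1 at 2.25-fold (adjusted p = 2.2e-07) higher as deposited, and oxidative stress defence had 9 of 29 members higher and 0 lower (13 and 3 adjusted over the list alone). Heat shock and chaperone genes had a median log2 fold change of 0.59 (adjusted p of the list = 3.4e-07). Oxidative stress defence genes had a median log2 fold change of 0.28 (adjusted p of the list = 0.0052 but 0.068 with an inter-gene correlation of 0.05). The thermogenic list had 3 of 26 members higher and 3 lower (3 and 4 adjusted over the list alone). Thermogenic programme genes had a median log2 fold change of 0.038 (adjusted p of the list = 0.810). De novo lipogenesis had 4 of 21 members higher and 3 lower (4 and 3 adjusted over the list alone). De novo lipogenesis genes had a median log2 fold change of 0.10 (adjusted p of the list = 0.330). Fatty acid oxidation had 6 of 30 members higher and 3 lower (9 and 4 adjusted over the list alone). Fatty acid oxidation genes had a median log2 fold change of 0.16 (adjusted p of the list = 0.031 but 0.138 by ranks and 0.186 with an inter-gene correlation of 0.05). Oxidative phosphorylation had 1 of 79 members higher and 6 lower (0 and 3 adjusted over the list alone), with small deposited folds such as 1.54 for Cox7b, and the mitochondrial ribosome had 9 of 58 members higher and 1 lower (10 and 1 adjusted over the list alone). Oxidative phosphorylation genes had a median log2 fold change of -0.18 (adjusted p of the list = 0.0015 but 0.0903 with an inter-gene correlation of 0.05). Mitochondrial ribosome genes had a median log2 fold change of 0.10 (adjusted p of the list = 0.0404 but 0.272 with an inter-gene correlation of 0.05).

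Among other cell types at 7 d, erythroid genes had 3 of 9 members higher and 0 lower (8 and 0 adjusted over the list alone). Erythroid genes had a median log2 fold change of 0.80 (adjusted p of the list = 0.0053). The deposited values of Hba-a1 and Hba-a2, of Hbb-b1 and Hbb-bs, and of Hbb-b2 and Hbb-bt were equal, as from shared reads of near-identical copies. Counted once, these left 6 members, with 2 higher and 0 lower (4 and 0 adjusted over the list alone), and an adjusted p of the list of 0.031 (0.077 with an inter-gene correlation of 0.05). Schwann cell and nerve genes had 0 of 9 members higher and 3 lower (0 and 3 adjusted over the list alone), with S100b 4.54-fold (adjusted p = 7.8e-21) lower and Erbb3 2.82-fold (adjusted p = 2.4e-05) lower in the deposited table, and smooth muscle and pericyte genes had 0 of 15 members higher and 2 lower (0 and 2 adjusted over the list alone). Schwann cell and nerve genes had a median log2 fold change of -0.81 (adjusted p of the list = 0.0082 but 0.120 by ranks). At 22 °C S100b was lower in KO as well, while the list median was 0.25 (adjusted p of the list = 0.566). S100b alone is therefore no measure of Schwann cells in this tissue. Smooth muscle and pericyte genes had a median log2 fold change of -0.31 (adjusted p of the list = 0.013 but 0.068 with an inter-gene correlation of 0.05). Interferon response genes had 4 of 26 members higher and 0 lower (5 and 0 adjusted over the list alone). Interferon response genes had a median log2 fold change of 0.41 (adjusted p of the list = 0.019 but 0.126 with an inter-gene correlation of 0.05). Extracellular matrix genes had 3 of 38 members higher and 5 lower (3 and 5 adjusted over the list alone). Extracellular matrix genes had a median log2 fold change of -0.39 (adjusted p of the list = 0.049 but 0.266 with an inter-gene correlation of 0.05). Macrophage genes had 0 of 25 members higher and 0 lower (0 and 0 adjusted over the list alone). Macrophage genes had a median log2 fold change of 0.0098 (adjusted p of the list = 0.897). Clock genes had 7 of 22 members higher and 2 lower (10 and 3 adjusted over the list alone), with the deposited Arntl 4.68-fold (adjusted p = 1.0e-10) higher. Circadian clock genes had a median log2 fold change of 0.23 (adjusted p of the list = 0.013 but 0.0796 by ranks and 0.0903 with an inter-gene correlation of 0.05). Immediate early genes had 3 of 20 members higher and 0 lower (3 and 0 adjusted over the list alone). These immediate early genes had a median log2 fold change of 0.51 (adjusted p of the list = 0.112 but 0.034 by ranks). The cell cycle inhibitor gene Cdkn1a was 4.26-fold (adjusted p = 6.1e-10) higher in the deposited table, in an apoptosis and senescence list with 3 of 18 members higher and 0 lower (5 and 1 adjusted over the list alone). Apoptosis and senescence genes had a median log2 fold change of 0.20 (adjusted p of the list = 0.362).

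**Figure D3:**
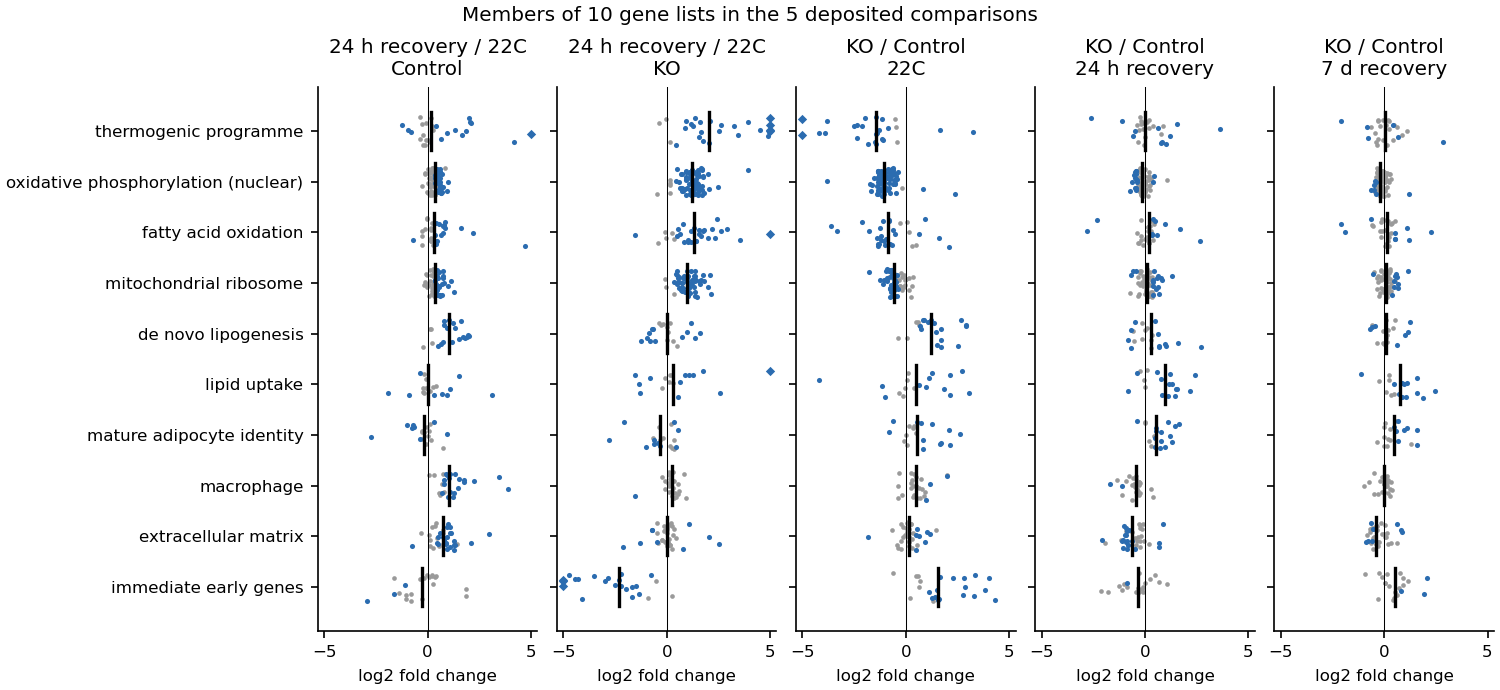
For 10 gene lists (vertical axis) and 5 comparisons (panels), each point is a member's log2 fold change from the authors' tables, in blue where its adjusted p is under 0.05 and in grey where it is not, with the list median as a black bar and diamonds at the edge for values beyond ±5. The medians of oxidative phosphorylation are -1.07 in KO against Control at 22 °C and 1.24 for recovery within KO.

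The KO comparisons at the 3 times used separate libraries, so their calls share no group. Over the 12224 genes listed at both 24 h and 7 d, 784 were higher in KO at both times, against 123 for independent lists, and 412 were lower at both, against 60.8. Between 22 °C and 24 h, 704 higher and 540 lower genes were shared, against 214 and 180.3, and between 22 °C and 7 d, 728 and 466, against 184 and 138. At all 3 times 535 genes were higher and 311 lower, where independence gives 19.9 and 11.1. Cidec, Lpl, Fabp4, Tbl1x and Tbl1xr1 were higher in KO at each time as deposited, and Hdac3, Ptgds, Gnas and Pccb were lower at each. Across genes, which are not independent replicates, Pearson's r of the deposited log2 fold changes was 0.424 between 22 °C and 24 h, 0.528 between 22 °C and 7 d and 0.597 between 24 h and 7 d.

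Whether the effect of the KO differed between 22 °C and recovery was tested for gene lists by a test added after the data were seen, which uses errors derived from the deposited p-values. The KO effect on thermogenic genes was higher after 24 h of recovery than at 22 °C by a median log2 difference of 1.75 (adjusted p of the list = 8.0e-35), and after 7 d by 1.65 (adjusted p of the list = 1.2e-31). Oxidative phosphorylation differed by 0.92 (adjusted p of the list = 3.5e-39) at 24 h and 0.90 (adjusted p of the list = 2.0e-39) at 7 d. De novo lipogenesis went the other way, by -0.95 (adjusted p of the list = 8.6e-10) at 24 h and -1.21 (adjusted p of the list = 4.0e-12) at 7 d. Immediate early genes differed by -1.72 (adjusted p of the list = 2.2e-06) at 24 h and -1.045 (adjusted p of the list = 0.024 but 0.106 with an inter-gene correlation of 0.05) at 7 d. Macrophage and extracellular matrix genes, which passed the list test of recovery in Control and not in KO, differed by -0.89 (adjusted p of the list = 1.7e-04) and -0.73 (adjusted p of the list = 8.1e-06) at 24 h. At 7 d these values were -0.38 (adjusted p of the list = 0.077 but 0.016 by ranks and 8.8e-04 on differences not divided by their errors) for macrophage genes and -0.46 (adjusted p of the list = 0.0033 but 0.060 with an inter-gene correlation of 0.05) for extracellular matrix genes. The tests at 24 h and 7 d used the same 22 °C libraries and are not independent, and no single gene was tested for such a difference.

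Recovery of 7 d against 22 °C was in no deposited table, so it is described from the deposited group means without a test of single genes, and its ratios share the 22 °C means with those at 24 h. The ranges of random lists hold the spread between genes and not that between libraries. A median outside such a range is therefore no test of a difference between groups. De novo lipogenesis in Control lay at a median log2 ratio of 1.44 above 22 °C at 7 d, outside the -0.056 to 0.32 of 95% of expression-matched random lists, and at 1.00 at 24 h. In KO the same list lay at 0.15 at 7 d. Fasn, the fatty acid synthase gene, had deposited means of 642 RPKM at 22 °C, 2429 at 24 h and 3378 at 7 d in Control, and 3219, 2023 and 3159 in KO. Acly, which cleaves citrate to acetyl-CoA, had deposited means of 191, 523 and 847 RPKM in Control. Thermogenic genes at 7 d lay at 0.022 in Control, within the -0.056 to 0.26 of random lists, and at 1.71 in KO, outside -0.056 to 0.55. Oxidative phosphorylation lay at 0.30 in Control, outside 0.021 to 0.22, and at 1.24 in KO, outside 0.068 to 0.47. The 19 cell cycle genes with a ratio at both times in Control lay at 0.72 at 24 h and -0.076 at 7 d, and 25 macrophage genes at 1.05 and 0.18.

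**Figure D4:**
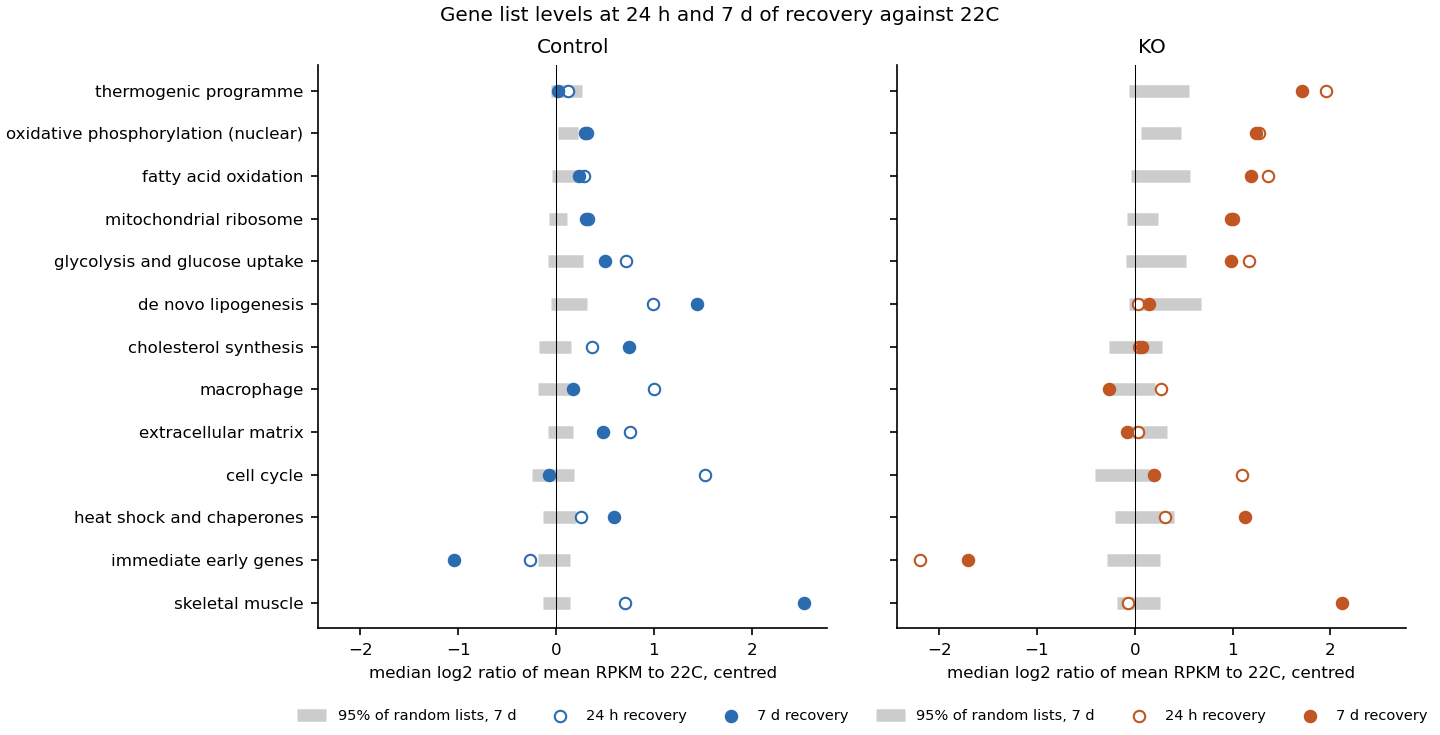
Medians over each list of the log2 ratio of mean RPKM to 22 °C, centred on all genes, are drawn for Control and KO at 24 h (open circles) and 7 d (filled circles) of recovery, over the members listed at each time (34 and 19 cell cycle genes in Control), with grey bars for 95% of the medians of random lists matched on expression at 7 d. De novo lipogenesis in Control lies at 1.44 at 7 d and the thermogenic list in KO at 1.71.

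Skeletal muscle genes, a sign of muscle taken with the fat pad, had no member past the threshold in any of the 5 deposited tables, and the list passed its test in none. Its median log2 fold change was 0.85 (adjusted p of the list = 0.585) for recovery in Control and -0.11 (adjusted p of the list = 0.816) for recovery in KO. For KO against Control it was 0.21 (adjusted p of the list = 0.856) at 22 °C, -0.65 (adjusted p of the list = 0.444) at 24 h and -0.20 (adjusted p of the list = 0.784) at 7 d. Set against 22 °C, group means at 24 h lay at a median log2 ratio of 0.70 in Control, outside the -0.16 to 0.15 of random lists, with 27 of 30 members above 0, and at -0.067 in KO. At 7 d they lay at 2.54 in Control and 2.11 in KO, with all 30 members above 0 in each. Lists that respond to tissue handling also lay away from 22 °C at 7 d, outside the range of random lists in both genotypes, with immediate early genes at -1.04 in Control and -1.71 in KO and heat shock genes at 0.59 and 1.12. Erythroid genes lay at -0.45 in Control, outside -0.22 to 0.29, and at 0.75 in KO, outside -0.30 to 0.59. Other levels set against 22 °C, at 7 d in both genotypes and at 24 h in Control, stand beside these differences.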

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

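All tests in this part were chosen after the results were seen, except the lower end of the length-matched random lists, whose bound was set before its value was known. Each value is the median over a list of the KO effect after recovery minus that at 22 °C, in log2, with the adjusted p of the list test, and each drew attention because this difference between times passed its test in every form tried first, namely by scores, by ranks, with an inter-gene correlation of 0.05 and without errors. Differences that passed by scores and missed in another form, such as those of inflammatory cytokines at 24 h and of extracellular matrix genes at 7 d, are left out. The 24 h and 7 d values share the 22 °C libraries.

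Mitochondrial and thermogenic lists differed upward at both times. The thermogenic programme differed by 1.75 (adjusted p of the list = 8.0e-35) at 24 h and 1.65 (adjusted p of the list = 1.2e-31) at 7 d, and oxidative phosphorylation by 0.92 (adjusted p of the list = 3.5e-39) and 0.90 (adjusted p of the list = 2.0e-39). Fatty acid oxidation differed by 0.89 (adjusted p of the list = 1.0e-17) and 0.92 (adjusted p of the list = 1.1e-17), the pyruvate and TCA cycle list by 1.02 (adjusted p of the list = 7.8e-16) and 0.93 (adjusted p of the list = 4.0e-14), and the mitochondrial ribosome by 0.68 (adjusted p of the list = 2.9e-17) and 0.62 (adjusted p of the list = 3.5e-17). At 7 d glycolysis differed by 0.53 (adjusted p of the list = 1.2e-06), and creatine and calcium cycling by 0.91 (adjusted p of the list = 0.0033). Heat shock genes differed by 0.50 (adjusted p of the list = 0.0025) and erythroid genes by 1.14 (adjusted p of the list = 0.0083, but 0.063 with globin genes of equal fold changes counted once) at 7 d. Downward were de novo lipogenesis, -0.95 (adjusted p of the list = 8.6e-10) at 24 h and -1.21 (adjusted p of the list = 4.0e-12) at 7 d, cholesterol synthesis, -0.61 (adjusted p of the list = 7.5e-08) at 7 d, and at 24 h immediate early genes, -1.72 (adjusted p of the list = 2.2e-06), macrophage genes, -0.89 (adjusted p of the list = 1.7e-04), and extracellular matrix genes, -0.73 (adjusted p of the list = 8.1e-06).

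Behind the mitochondrial difference stands the lower level in KO at 22 °C. Against the authors' normalization as its cause, oxidative phosphorylation lay at -1.31 in plain ratios of mean RPKM, and against exchanged labels, Hdac3 was lower there by a log2 fold change of -1.37. Fewer adipocytes in the pad would lower adipocyte markers too, and the mature adipocyte list had a median of 0.55. The same list was also higher in KO at 24 h (0.55) and at 7 d (0.47), where the thermogenic list did not pass its test. Higher expression of these genes in KO could hide a smaller share of adipocytes, so this explanation stays open. Loss of short transcripts was excluded as the whole cause, since the list median of -1.07 lay below each of 10000 random lists matched on length and expression, of which 95% lay between -0.27 and -0.048. A part of the drop from it stays open, as the lower end of -0.27 missed the bound of -0.25 set beforehand. A larger share of white adipocytes stays open, as 2 of its markers past the threshold were lower and 5 higher and they are too few to decide. The genotype, which the design names, stays among the open explanations and was not tested apart from these.

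Immediate early genes were higher in KO at 22 °C. The authors' normalization was excluded as the cause, since the list median was 1.28 in ratios of mean RPKM. Rougher or slower handling of the tissue in that group may raise such genes; heat shock genes had a median of -0.025, but they can part from immediate early genes under handling, so handling and genotype cannot be told apart here.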

How the results depend on the processing

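The authors' own calls, adjustment over listed genes, ratios of mean RPKM, the inter-gene correlation of 0.05 and the other pseudocount were chosen after the results were seen. No paired analysis was possible because the tables carry no replicate numbers. A second count test, leaving out single libraries, other scaling, a fit of all 24 libraries, an estimated inter-gene correlation and other splits of the samples were not run. The depth of 4.64e+06 to 1.25e+07 reads per library limits genes near the listing minimum.

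Counts of higher and lower genes stayed within 1.5 times under adjustment over listed genes and an average log2 CPM of at least 1. Ratios of mean RPKM were used only for the direction of the same calls, none of which changed. That setting could gain or lose no call, so it does not show how the counts depend on scaling. Smaller counts followed from stricter thresholds by construction. With an absolute log2 fold change of at least 1 they were 484 and 217 (recovery in Control), 1050 and 782 (recovery in KO), 770 and 748 (KO against Control at 22 °C), 282 and 248 (24 h) and 264 and 177 (7 d). By the authors' own calls they were, in that order, 830 and 457, 1815 and 1466, 1264 and 1397, 649 and 416, and 583 and 328. With an adjusted p under 0.01 they were 1094 and 617 for recovery in Control, 880 and 525 for KO at 24 h and 411 lower for KO at 7 d. Pearson's r of KO effects among genes past 0.05 in either table was 0.545 (22 °C and 24 h), 0.661 (22 °C and 7 d) and 0.817 (24 h and 7 d), and the last was 0.740 with an average log2 CPM of at least 1. For these correlations the cause was not tested. Lists past 0.05 with an inter-gene correlation of 0.05 numbered 7 in place of 21 for KO at 24 h and 9 in place of 17 at 7 d. Of single list tests 41 lost their call with that correlation, 17 by ranks, where 13 gained one, and 5 without low genes. Counting members with equal fold changes once ended 2 erythroid calls. Of the calls of named genes, 50 missed 0.01 and 251 a log2 fold change of 1. Of the 7 d medians, 7 moved by over 0.2 with a pseudocount of 1. The thermogenic list in KO then lay at 1.43 and skeletal muscle in Control at 2.26. The median of T, B and NK cell genes in KO at 7 d reversed from -0.89 to 0.017 without low genes, which left fewer members.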

Other observations

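Gene groups not yet described did not pass the list test by scores in the comparisons given here. Secreted factors of brown fat had 2 of 14 members higher and 5 lower (2 and 5 adjusted over the list alone) for recovery in KO, where the deposited Igf1 was 3.45-fold (adjusted p = 1.5e-12) lower. Genes of these secreted factors had a median log2 fold change of -0.17 (adjusted p of the list = 0.604). For recovery in Control the same list had 3 of 14 members higher and 1 lower (3 and 2 adjusted over the list alone), where Angptl4, an inhibitor of lipoprotein lipase, was 3.71-fold (adjusted p = 1.2e-10) lower in the deposited table. Genes of these secreted factors had a median log2 fold change of 0.39 (adjusted p of the list = 0.347). Glycogen genes had 11 of 19 members higher and 3 lower (11 and 3 adjusted over the list alone) for recovery in KO, with the deposited synthase gene Gys2 7.89-fold (adjusted p = 1.2e-16) higher and the phosphorylase gene Pygb 4.13-fold (adjusted p = 8.6e-41) lower. Glycogen metabolism genes had a median log2 fold change of 0.35 (adjusted p of the list = 0.10 but 0.031 by ranks). Adrenergic signalling had 12 of 29 members higher and 4 lower (12 and 4 adjusted over the list alone) for recovery in KO, with the adenylyl cyclase genes Adcy3 5.84-fold (adjusted p = 3.7e-30) higher and Adcy5 6.04-fold (adjusted p = 6.5e-15) lower as deposited. Adrenergic signalling genes had a median log2 fold change of 0.13 (adjusted p of the list = 0.227). Adcy3 was also 3.31-fold (adjusted p = 1.2e-13) higher in Control in the deposited table. Adipocyte transcription factors had 8 of 32 members higher and 10 lower (8 and 12 adjusted over the list alone) for recovery in KO, other histone deacetylases 1 of 16 members higher and 3 lower (1 and 3 adjusted over the list alone) in KO against Control at 22 °C, and lymphatic endothelium 0 of 5 members higher and 0 lower (0 and 0 adjusted over the list alone) in KO against Control at 24 h. Adipocyte transcription factor genes had a median log2 fold change of -0.13 (adjusted p of the list = 0.794). Other histone deacetylase genes had a median log2 fold change of -0.16 (adjusted p of the list = 0.267). Lymphatic endothelium genes had a median log2 fold change of -0.12 (adjusted p of the list = 0.632). No member of the list of mitochondrial-encoded transcripts was listed.

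All tests in this paragraph were chosen after the results were seen. The hypothesis was that genes called at 24 h of recovery still lie away from 22 °C at 7 d, tested across genotypes so that no library is shared. Of the genes higher in KO at 24 h, 2727 had a centred log2 ratio to 22 °C in Control at both times. Their median was 0.29 at 24 h (0.30 over 2756 with a ratio then). At 7 d it was 0.22, with 95% of random lists between 0.0081 and 0.040. This range lacks library spread, so chance in 22 °C libraries stays open. Over the 2395 genes lower in KO the medians in Control were -0.29 and -0.21, and genes called in Control lay in KO at 0.74 and 0.57 where higher (1594 genes) and -0.53 and -0.43 where lower (1063 genes). A lasting effect of the cold, or 22 °C groups handled apart from the recovery groups, could also give such values. The causes cannot be told apart. Handling lists were away from 22 °C at 7 d too, with immediate early genes at -1.04 in Control and -1.71 in KO and heat shock genes at 0.59 and 1.12. The question stays open because every ratio uses the 22 °C groups. The labels do not say whether these were kept beside the recovery groups, and they name no separate group without cold for 7 d.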
